A study of Arabidopsis thaliana with 12 samples.

How the data were processed

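RNA from whole Arabidopsis thaliana seedlings of the Col-0 background was measured on Affymetrix AraGene 1.1 ST arrays, 1 array per sample. The 12 arrays fell into 4 groups of 3: wild type with the solvent DMSO at 1%, wild type with 30 µM hyperphyllin, amp1-13 with DMSO at 1%, and amp1-13 with 30 µM hyperphyllin. Groups and replicate numbers were taken from the labels, which call the 3 samples of each group biological replicates.

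The deposited values were log2 expression values that the authors obtained with RMA, per the submitters' processing notes. RMA corrects background, normalizes arrays between each other and summarises the probes of a transcript cluster (here called a probe set). The RMA software, its version and its probe definitions were not given in the sources used here. Per the values themselves, the range was 0.593 to 12.731 and the array medians over all probe sets lay between 4.05 and 4.18, so no further transformation or normalization was applied. Scanner intensities were not analysed here, so the signal over background of single probes is unknown. The number of arrays limits the precision.

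The value table held 38408 probe sets. The annotation table paired 17504 of them (45.6%) with a gene: 16746 with 1 gene and 758 with several. The other 20904 were unnamed here, which does not mean that they lack a gene. Of the probe sets with 1 gene, 16601 matched a locus of the RefSeq gene table of assembly TAIR10.1, which was used only for names and for which genes neighbour each other, and 145 did not match. A symbol of its own was present for 1826 of them, and 14920 carried a locus code only. The main tests covered the 17504 probe sets with a gene, each of which is counted as a gene below. Genes with several probe sets were represented in lists and in the text by the probe set with the highest mean over the 12 arrays. No probe set with several genes was named. AMP1, CYP78A5 and CYP78A7 were not analysed here, since no named probe set stood for them.

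A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, with 8 residual degrees of freedom and an estimated prior of 3.9), so that the 4 groups shared an estimate of the spread. The comparisons were hyperphyllin against DMSO in wild type, hyperphyllin against DMSO in amp1-13, amp1-13 against wild type in DMSO, amp1-13 against wild type in hyperphyllin, the interaction of genotype and treatment, and hyperphyllin-treated wild type against DMSO-treated amp1-13. Adjusted p values are those of limma with Benjamini-Hochberg adjustment over the 17504 probe sets. A gene is said to have risen, fallen or changed where the adjusted p was under 0.05. Fold changes are differences of mean log2 values, given with the standard error (SE) of the fit, and every such value compares 3 arrays with 3. A further count asked for a change of at least 2-fold.

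The design, the gene lists and the alternatives were fixed before the data were examined, apart from those said to be chosen later. The rule for named genes took, per comparison, the 10 genes with the highest and the 10 with the lowest fold change among genes that passed, whose arrays did not overlap between the groups and whose probe set had exactly 1 gene with a symbol of its own. For the interaction it took 5 each way. It also took up to 4 members of each gene list with the smallest p in that comparison, whatever the p. It added AMP1, its homologue LAMP1, CYP78A5 and CYP78A7. A list member whose symbol the annotation gave to another locus was left out, which concerned 7 members. Of 469 genes written in 27 lists, 72 were measured, and the 11 lists with at least 3 measured members were tested. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 11 lists. Camera with an estimated correlation and limma's fry were the alternatives. Fry asks only whether a list's genes move on balance in 1 direction. For each list the number of members past 0.05 when adjusted over the list alone was also counted. Gene families made from shared symbol beginnings (8 or more probe sets), together with the genes of the chloroplast genome, gave 37 further sets that were chosen after seeing the data and tested in the same way.

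The tests were first tried on simulated data: 200 of 17504 probe sets were changed in the simulated comparison of hyperphyllin with DMSO in wild type. Of those with a true log2 change of 0.5, 21 of 67 (31.3%) were recovered, of those with a change of 1, 55 of 67 (82.1%), and of those with a change of 2, 63 of 66 (95.5%). Of the 146 calls in that simulation, 7 (4.79%) were of unchanged probe sets. A list shifted by 0.5 was recovered and 0 of the other lists were called. The simulated genes varied independently of each other and with the same spread in all groups. In the data the estimated correlation reached 0.589 for the auxin response list. The simulation therefore cannot show how often lists of genes that vary together are called wrongly. In the data the median SD was 0.188 in wild type with DMSO, against 0.121 to 0.134 in the other groups. The simulated shares of recovered and wrongly called genes therefore need not hold for the data. Comparisons that shared the wild-type DMSO arrays were set beside 100 simulations of unchanged groups.

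The alternatives were the replicate number as a block, a fit of the compared groups alone, a trended and robust prior, array weights (statmod 1.5.0), removal of the dimmest 30% of probe sets, quantile normalization, centring on the array medians, all 38408 probe sets, 1 probe set per gene, an adjusted p of 0.01, a change of at least 2-fold in both parts of an overlap, and leaving out each array in turn. Fits without DMSO array 1 of wild type for comparisons that do not use it, and fits without DMSO arrays 2 and 3 of wild type, were added after seeing the data. Annotation tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.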

Results

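Transcript levels were measured on 12 arrays from whole Arabidopsis seedlings grown for 10 d in liquid medium. Wild type and the mutant amp1-13, both in the Col-0 background, received either the solvent DMSO or 30 µM hyperphyllin, with 3 arrays per group. AMP1 encodes a putative carboxypeptidase of the endoplasmic reticulum, and loss of it enlarges the shoot meristem and speeds up leaf formation. Hyperphyllin is a small molecule known to give wild-type seedlings features of amp1 mutants. The design therefore asks what the compound changes in wild type, whether it acts when AMP1 is mutated, and how the chemical and the genetic condition compare. Of 38408 probe sets, 17504 carried a gene name and were tested. AMP1 itself was not analysed here, so the genotype of the arrays was not checked through it. LAMP1 (AT5G19740), a homologue of AMP1, did not pass the test in any of the 6 comparisons; its log2 difference between amp1-13 and wild type in DMSO was -0.24 ± 0.14 (SE, 3 arrays per group, limma adjusted p = 0.428). Without DMSO array 1 of wild type LAMP1 was at -0.43 there (adjusted p = 0.0161) and at -0.65 with hyperphyllin in wild type (adjusted p = 0.00145), so these calls depended on that array.

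The array medians lay between 4.13 and 4.18 (log2) over the named probe sets. Principal component 1 held 40.4% of the variance between arrays and set DMSO arrays 2 and 3 of wild type (scores 43.9 and 47.7) apart from the other 10 arrays, which lay between -28.1 and 0.78. DMSO array 1 of wild type lay among those, at -9.82. Its mean correlation with the other arrays of its group was 0.973, against 0.987 with the arrays of the other groups. The counts of called genes below are therefore also given without DMSO array 1 of wild type.

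**Figure D1:**
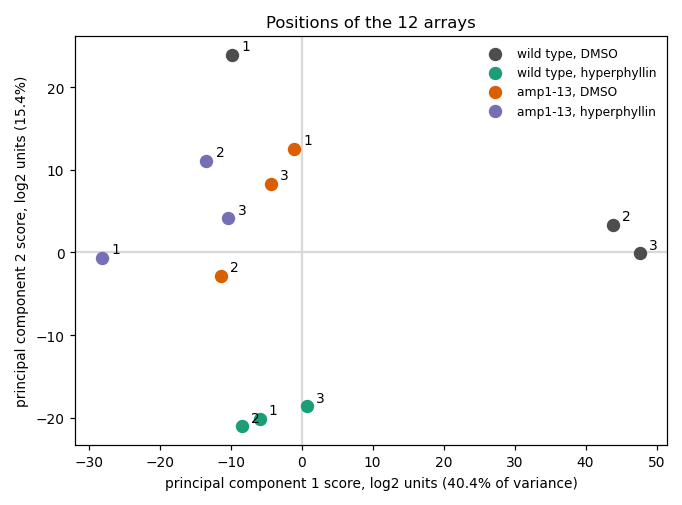
Scores of the 12 arrays on principal components 1 and 2 of the log2 values of 17504 probe sets, coloured by group and numbered by replicate. DMSO arrays 2 and 3 of wild type lie at 43.9 and 47.7 on component 1, and DMSO array 1 of wild type at -9.82.

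In wild type with hyperphyllin, the zinc-finger gene STZ, a repressor induced by many stresses, rose by 3.29 ± 0.64 (log2, SE, 3 arrays per group, limma adjusted p = 0.0291). PUB23, which encodes a U-box ubiquitin ligase of stress signalling, rose by 1.62 ± 0.36, and the defensin-like gene PDF1.4 by 2.05 ± 0.21. PORB, a protochlorophyllide oxidoreductase of chlorophyll synthesis, rose by 1.17 ± 0.14 (adjusted p = 0.00324). TAPX, the thylakoid ascorbate peroxidase, rose by 0.80 ± 0.09 (adjusted p = 0.00324).

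The other named genes that rose were AR781 (1.81), the purine permease gene PUP18 (1.38), CHL, which encodes a lipocalin of the chloroplast (1.03), the tetraspanin gene TET8 (0.82) and PWD, a dikinase of starch breakdown (0.82). Among the genes that fell, BGLU47, a beta-glucosidase gene, changed by -1.42 ± 0.21, the xyloglucan-modifying gene XTH21 by -0.89 ± 0.18 and the endoglucanase gene GH9B13 by -0.77 ± 0.11. GH3.17, which conjugates auxin to an amino acid, changed by -0.81 ± 0.12 (adjusted p = 0.0123), and IDL4, a gene of IDA-like signalling peptides, by -1.02 ± 0.12 (adjusted p = 0.0031). SP1L4 (-1.18), BPEp (-0.84), ANX2 (-0.66), TBL38 (-0.62) and BIM1, a partner of brassinosteroid-responsive factors (-0.55), also fell.

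In all, 287 genes changed with hyperphyllin in wild type, 203 up and 84 down, and 102 of them by at least 2-fold (86 up, 16 down). Without DMSO array 1 of wild type the count was 2449, 1103 up and 1346 down, and it held all of the 287 with the same sign. With other arrays left out it was 27 without DMSO array 2, 108 without DMSO array 3, and 72, 23 and 56 without hyperphyllin arrays 1, 2 and 3. The count of at least 2-fold changes moved from 102 to 626 without DMSO array 1, 19 and 37 without DMSO arrays 2 and 3, and 36, 18 and 29 without hyperphyllin arrays 1, 2 and 3. Of the 20 named genes, IDL4, PDF1.4, PORB and TAPX kept their call with each of these 6 arrays left out.

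Among the 11 gene lists, the stomatal lineage markers and the photosynthesis genes were shifted upwards in wild type with hyperphyllin. All 4 measured stomatal genes had higher means, SPCH by 0.79 ± 0.28 and FAMA by 0.43 ± 0.19, though none passed the test alone; camera gave an adjusted p of 0.029, and the adjusted p was 0.173 with an estimated correlation. SPCH and FAMA encode factors that start and end the stomatal lineage. Of the 3 photosynthesis genes, PSAE-1 of photosystem I rose (0.55 ± 0.10, limma adjusted p = 0.025) and LHCB4.1 was at 0.40 ± 0.13 without passing. RCA, the rubisco activase gene, was at -0.01 ± 0.08, so the upward shift rested on 2 of the 3 measured members. For this list camera gave an adjusted p of 0.0315, against an adjusted p of 0.471 with an estimated correlation. Without DMSO array 1 of wild type SPCH (adjusted p = 0.00649) and LHCB4.1 (adjusted p = 0.0128) passed, while FAMA lay at 0.19. Adjusted over the list alone, 2 photosynthesis genes and 0 stomatal genes passed. Over all alternatives the adjusted p of the stomatal list ran from 0.0138 to 0.173 and that of the photosynthesis list from 0.0138 to 0.471. Both lost their call without DMSO array 3 of wild type (adjusted p = 0.074 each), and the photosynthesis list also without hyperphyllin array 3 (0.0608). The count of shifted lists was 2, against 4 without DMSO array 1, 0 without DMSO array 3 and 1 without hyperphyllin array 3. The other 9 lists had adjusted p values from 0.237 to 0.901.

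Cytokinin and meristem genes, which are of interest for amp1, were measured in small number. The cytokinin glucosyltransferase gene UGT76C2 was 0.56 ± 0.14 higher with hyperphyllin in wild type (adjusted p = 0.0631) and the response regulator gene ARR16 0.71 ± 0.29 higher (adjusted p = 0.222), while their relatives UGT76C1 and ARR15 had lower means with the compound; none of the 4 passed. LAS, a gene of axillary meristem formation, was at -0.41 ± 0.14 (adjusted p = 0.163). The root hair expansin gene EXPA7 was at -0.99 ± 0.35 (adjusted p = 0.166), and this difference lay at 0.02 when DMSO array 1 stood alone for its group. Without that array EXPA7 (-1.50, adjusted p = 7.69e-04) and UGT76C2 (0.66, adjusted p = 0.00803) passed, and LAS lay at -0.23.

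**Figure D2:**
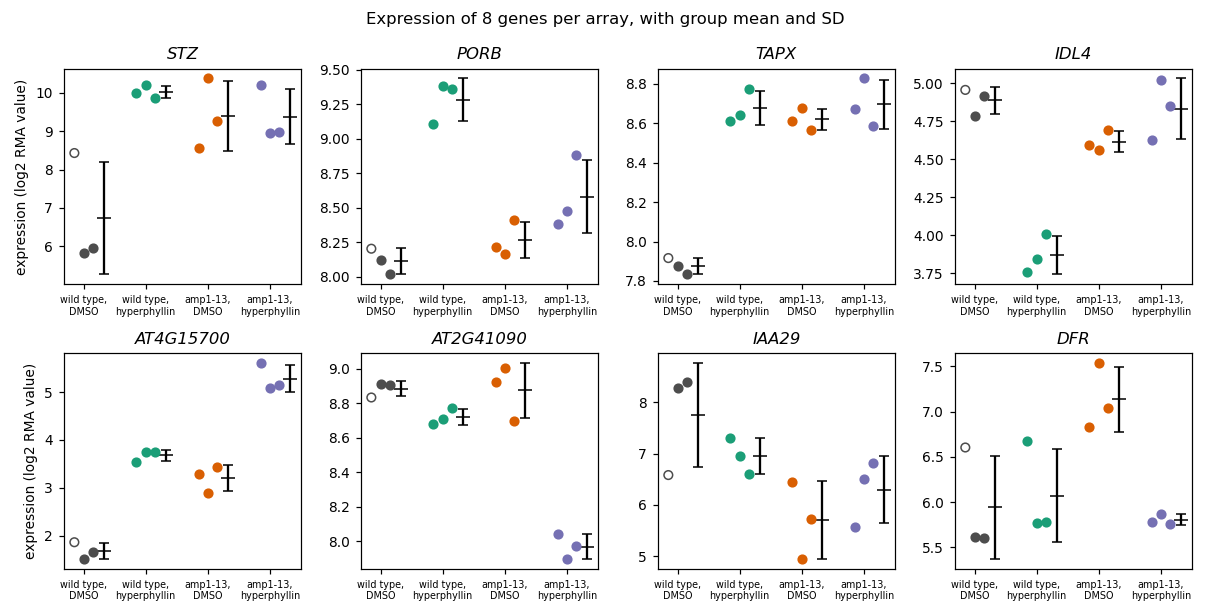
Log2 expression of 8 genes on each of the 12 arrays, by group, with the group mean (dash) and SD (bars); the open circle is DMSO array 1 of wild type. AT4G15700 lay at group means of 1.68 and 3.67 in wild type without and with hyperphyllin and at 5.28 in treated amp1-13, and STZ lay at 8.43 on DMSO array 1 of wild type against 5.81 and 5.96 on arrays 2 and 3.

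In amp1-13, hyperphyllin changed 3 genes. All 3 carried a locus code only and so lay outside the rule for named genes; they are named here after their values were seen. AT4G15700 and AT4G15660, neighbouring genes of CC-type glutaredoxins, rose by 2.08 ± 0.17 and 2.06 ± 0.17 (log2, SE, 3 arrays per group, limma adjusted p = 3.96e-04 each). AT2G41090, which encodes a calmodulin-like protein, changed by -0.91 ± 0.10 (adjusted p = 0.00536). Both glutaredoxin genes also rose in wild type, AT4G15700 by 2.00 ± 0.17 and AT4G15660 by 0.94 ± 0.17 (adjusted p = 0.0226). The 2 genes are close copies of each other, and whether their probes tell them apart was not determined.

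The stem cell gene CLV3 was 1.04 ± 0.27 higher with hyperphyllin in amp1-13 and the anthocyanin gene DFR was at -1.33 ± 0.30, without passing the test (adjusted p = 0.249 and 0.185). CLV3 was dim: its amp1-13 means of 2.37 in DMSO and 3.41 in hyperphyllin lay below the median of every array. Both glutaredoxin genes kept their call with each of the 6 amp1-13 arrays left out, while AT2G41090 lost it without DMSO array 1 of amp1-13 (adjusted p = 0.0501); the count of changed genes ran from 2 to 5. The 5 came without hyperphyllin array 3 of amp1-13, which also moved the count of changes of at least 2-fold from 2 to 4. Taking DMSO array 1 of wild type out of the estimate of the spread gave 138 changed genes, 46 up and 92 down, 23 of them by at least 2-fold; the 3 genes were among them.

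The flavonoid and anthocyanin genes were shifted downwards by hyperphyllin in amp1-13. All 6 measured members had lower means and none passed over all genes; DFR was lowest and UGT78D1, a flavonol glycosyltransferase gene, was at -0.28 ± 0.12. Camera gave an adjusted p of 0.018, and the adjusted p was 0.475 with an estimated correlation and ran from 0.0107 to 0.475 over all alternatives. Adjusted over the list alone, 1 member passed. The call was lost without DMSO array 2 of amp1-13 (adjusted p = 0.226) and without hyperphyllin array 3 of amp1-13 (adjusted p = 0.12). The other 10 lists had adjusted p values from 0.104 to 0.972. The count of shifted lists was 1, with 3, 0 and 2 without DMSO arrays 1, 2 and 3 and 3 and 0 without hyperphyllin arrays 1 and 3 of amp1-13.

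Without the compound, TAPX was 0.74 ± 0.09 higher in amp1-13 than in wild type (log2, SE, 3 arrays per group, limma adjusted p = 0.0271). CCB3, a gene of cytochrome b6f assembly, was 0.87 ± 0.16 higher (adjusted p = 0.0484). The subtilase gene SBT4.12 was 1.13 ± 0.21 higher, the osmotin gene OSM34 0.88 ± 0.16, and the xyloglucan-modifying gene EXGT-A3 0.80 ± 0.14. The sugar transporter gene SFP1 (0.71), ATSBT5.2 (0.71), UGT85A2 (0.69), the mannan synthase gene CSLA03 (0.69) and SCPL34 (0.62) were also higher. ANX2, a receptor kinase gene, was the only named gene that was lower, at -0.54 ± 0.10.

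A difference between the genotypes in DMSO was called for 57 genes, 45 higher and 12 lower in amp1-13, and 15 of them differed by at least 2-fold. Among all 38408 probe sets the count was 27, of which 6 were higher and 21 lower. Which direction held most calls therefore depended on the probe sets tested, while the sign of each gene's own difference did not. Without DMSO array 1 of wild type 2672 genes differed, 1252 higher and 1420 lower, all of the 57 among them with the same sign. It was 0 and 6 without DMSO arrays 2 and 3 of wild type and 16, 1 and 0 without DMSO arrays 1, 2 and 3 of amp1-13. The count of at least 2-fold differences was 612, 0 and 3 without wild-type arrays 1, 2 and 3, and 1 and 0 without arrays 2 and 3 of amp1-13. None of the 11 named genes kept its call with each of these 6 arrays left out.

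Genes of early auxin response were shifted downwards in amp1-13 in DMSO. Of 8 measured members, 7 had lower means and 0 passed over all genes, while 5 passed in that direction when adjusted over the list alone. IAA29 was at -2.05 ± 0.50, LBD29 at -1.74 ± 0.58, GH3.1 at -1.57 ± 0.44 and GH3.3 at -0.97 ± 0.29; IAA29 encodes an Aux/IAA repressor, and GH3 enzymes conjugate auxin. Camera gave an adjusted p of 0.00148 and, with an estimated correlation, an adjusted p of 0.312. The call held with each of the 6 arrays left out, but the adjusted p was 0.948 when DMSO array 1 stood alone for wild type, and LBD29 then lay at 0.02. Without that array IAA29 (-2.63, adjusted p = 0.00135), LBD29 (-2.61), GH3.1 (-2.30) and GH3.3 (adjusted p = 0.0139) passed. The alternatives ran from 5.73e-06 to 0.948.

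A further 3 lists were shifted upwards in amp1-13 in DMSO, each with an adjusted p of 0.312 with an estimated correlation. All 6 flavonoid genes had higher means, DFR by 1.19 ± 0.30 (list adjusted p = 0.00822; alternatives from 0.00135 to 0.879), and 1 passed over the list alone. All 3 photosynthesis genes had higher means, LHCB4.1 by 0.42 ± 0.13 and PSAE-1 by 0.35 ± 0.10 (list adjusted p = 0.00822; alternatives from 0.00252 to 0.428), and 2 passed over the list alone. Of 5 genes of the unfolded protein response 4 had higher means, among them the chaperone gene BIP1 at 0.71 ± 0.24 and ERDJ3B at 0.25 ± 0.11 (list adjusted p = 0.0434; alternatives from 0.0161 to 0.312), and 0 passed over the list alone. None of these members passed over all genes; without DMSO array 1 of wild type DFR, LHCB4.1 and PSAE-1 did (adjusted p = 0.00197, 0.0104 and 0.0158) and BIP1 lay at 0.36. With array 1 alone for wild type the flavonoid list turned to -0.0317. The flavonoid call was lost without DMSO array 2 of amp1-13 (adjusted p = 0.0523) or DMSO array 3 of wild type (0.0927). That of the unfolded protein response was lost without DMSO arrays 2 and 3 of amp1-13 (0.139 and 0.0731) or 1 and 3 of wild type (0.0944 and 0.0581). The count of 4 shifted lists fell to 2 without DMSO array 2 of amp1-13 and without DMSO array 3 of wild type. The other 7 lists had adjusted p values from 0.0666 to 0.909.

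**Figure D3:**
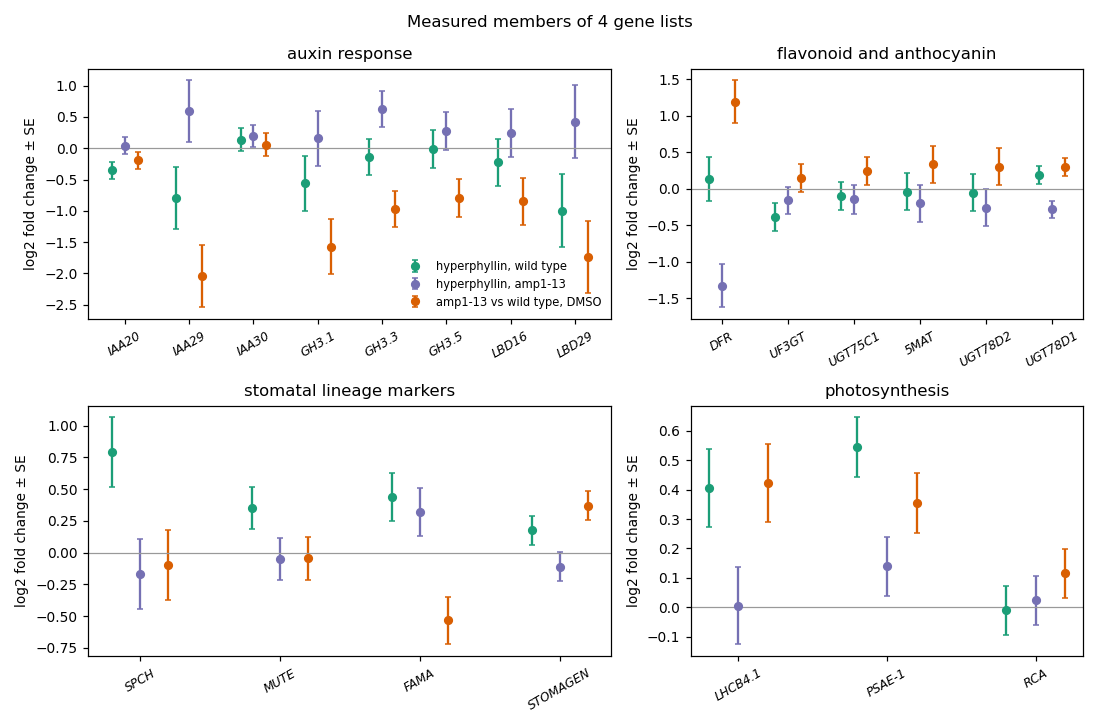
Log2 fold change with SE (bars) of the measured members of 4 gene lists in 3 comparisons, with 3 arrays per group. The auxin response genes lie below 0 for amp1-13 against wild type in DMSO, with IAA29 at -2.05 as the lowest and IAA30 as the member above 0.

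In hyperphyllin, amp1-13 had higher levels than wild type of IDL4 and GH3.17, which the compound had lowered in wild type. IDL4 was 0.96 ± 0.12 higher in amp1-13 (log2, SE, 3 arrays per group, limma adjusted p = 0.0123) and GH3.17 0.76 ± 0.12 higher (adjusted p = 0.036). SCPL34, a carboxypeptidase-like gene, was 0.70 ± 0.11 higher, and MCCB, a carboxylase of leucine breakdown, 0.54 ± 0.09. The calmodulin-binding gene iqd21 was at -0.64 ± 0.11 (adjusted p = 0.0404). Outside the rule, chosen after their values were seen, the glutaredoxin genes AT4G15680, AT4G15700 and AT4G15660 were 1.86, 1.61 and 1.52 higher in amp1-13, and AT2G41090 was at -0.75 (adjusted p = 0.0163).

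In total 40 genes differed between the genotypes in hyperphyllin, 21 higher and 19 lower in amp1-13, and 17 of them by at least 2-fold. CLV3 was 1.49 ± 0.27 higher in amp1-13 with an adjusted p of 0.0511 and so did not pass. Its means in hyperphyllin, 1.92 in wild type and 3.41 in amp1-13, lay below the median of every array. SPCH was at -1.06 ± 0.28 (adjusted p = 0.161). With DMSO array 1 of wild type taken out of the estimate of the spread 577 genes differed, 308 higher and 269 lower and 83 by at least 2-fold, including the 40. The count was 5, 1 and 11 without hyperphyllin arrays 1, 2 and 3 of amp1-13 and 4, 2 and 10 without those of wild type, and none of the 5 named genes kept its call with each of them left out.

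A difference between the genotypes in their response to hyperphyllin was called by limma for 0 genes; 1448 genes had an unadjusted p under 0.05, and the lowest adjusted p was 0.128. The interaction was 1.38 ± 0.38 for CLV3 (adjusted p = 0.371), which was 1.04 higher with the compound in amp1-13 and at -0.34 in wild type. It was -1.46 ± 0.42 for DFR (adjusted p = 0.403) and -0.96 ± 0.39 for SPCH (adjusted p = 0.552). Without DMSO array 1 of wild type CLV3, DFR and SPCH passed (adjusted p = 0.0485, 0.0205 and 0.0481). The interaction of CLV3 was then smaller, at 1.01, while those of DFR and SPCH were larger in size, at -1.79 and -1.29. CLV3 was dim, with group means from 1.92 to 3.41, below the median of every array. The other limma settings also gave 0 calls, except for array weights (290), the fit without DMSO array 1 of wild type (482) and the fit with array 1 alone in its group (262).

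**Figure D4:**
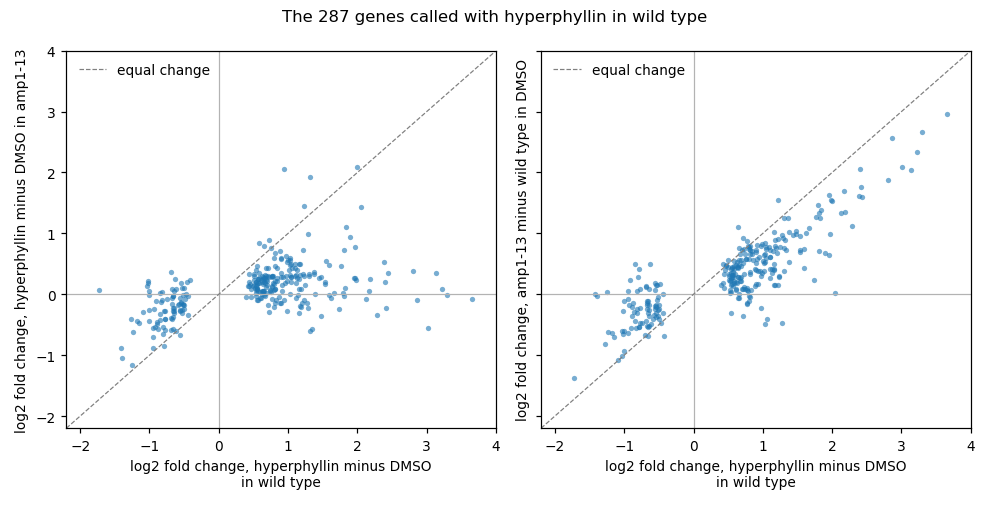
Log2 fold changes of the 287 genes called with hyperphyllin in wild type, plotted against the hyperphyllin response in amp1-13 (left) and the difference between amp1-13 and wild type in DMSO (right); the dashed line marks equal change. The median change in the wild-type direction was 0.81 in wild type and 0.22 in amp1-13; the right panel shares the wild-type DMSO arrays between its axes, which by itself favours equal signs.

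For the lists, the interaction was shifted upwards for the auxin response genes (all 8 higher, adjusted p = 0.0442) and downwards for the stomatal lineage markers (all 4 lower, adjusted p = 0.0442). With an estimated correlation the adjusted p values were 0.444 and 0.248, and over all alternatives they ran from 7.09e-06 to 0.444 and from 0.0201 to 0.248. Adjusted over the list alone, 0 members of either list passed. The auxin call held with 4 of 12 arrays left out in turn and the stomatal call with 5, and the count of 2 shifted lists was 4 without DMSO array 1 of wild type. With array 1 alone for its group the auxin list turned to -0.22. The count of shifted lists was 0 without DMSO arrays 1 and 2 of amp1-13 and DMSO arrays 2 and 3 of wild type. It was also 0 without hyperphyllin arrays 1 and 2 of wild type. It was 1 without hyperphyllin arrays 1 and 3 of amp1-13 and hyperphyllin array 3 of wild type. The other 9 lists had adjusted p values from 0.0645 to 0.918.

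Hyperphyllin-treated wild type was then set against DMSO-treated amp1-13, a comparison of the chemical with the genetic condition that shares no control. PDF1.4 was 2.02 ± 0.21 higher in the treated wild type (log2, SE, 3 arrays per group, limma adjusted p = 0.00378), the nitrate transporter gene NRT2.5 1.99 ± 0.40 and PORB 1.02 ± 0.14 (adjusted p = 0.00672). FAMA (listed as FMA), the regulator of guard cell fate, was 0.97 ± 0.19 higher. ICL, the isocitrate lyase gene (0.94), the glutamate receptor-like gene GLR3.5 (0.92), APL4 of starch synthesis (0.89), PWD (0.85), SD1-29 (1.43) and IQD22 (1.00) were also higher. MT1B, a metallothionein gene, was at -2.36 ± 0.35, the cellulose synthase-like gene CSLB03 at -1.79 ± 0.32 and NDB4, an alternative NADH dehydrogenase gene, at -1.44 ± 0.23. BGLU47 (-1.42), SFP1 (-1.14), OSM34 (-1.13), TBL38 (-1.12), ACT11 (-0.96), GH3.17 (-0.86) and AOR (-0.75) were also lower in the treated wild type.

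This comparison called 177 genes, 71 higher and 106 lower in hyperphyllin-treated wild type, and 63 of them by at least 2-fold. Without DMSO array 1 of wild type in the estimate of the spread it called 633, 267 higher and 366 lower and 107 by at least 2-fold, including all of the 177. The count was 99 and 74 without DMSO arrays 1 and 3 of amp1-13 and 88, 39 and 76 without hyperphyllin arrays 1, 2 and 3 of wild type. GH3.17, PDF1.4, PORB, PWD, SFP1 and TBL38 kept their call with each of the 6 compared arrays left out.

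The hyperphyllin response of wild type and the amp1-13 difference in DMSO shared 20 genes called in the same direction, 15 up and 5 down, and 0 in opposite directions. TAPX rose in both and ANX2 fell in both. Independent lists of these sizes would share 0.522 genes up and 0.0576 down, a number that does not allow for the shared DMSO arrays. Across genes, which are not independent replicates, the fold changes correlated with r = 0.684. Over 100 simulations of unchanged groups against the shared arrays, r averaged 0.482 and ran from -0.774 to 0.961. These simulations mixed the deviations of all arrays, DMSO array 1 of wild type included, into every group. In the data that deviation sits in 1 group, so the simulated ranges cannot decide. Nor can the 0 genes that the simulations called in both, against the real 20. The covariance was 0.0674 against a simulated mean of 0.0181, a difference of 0.0493, and lay within the simulated range from -0.00924 to 0.0874. The 3 shared control arrays could not be split into parts of at least 2, so part or all of this difference may come from them. Over all genes 72.5% had the same sign in both comparisons, against 67.4% on average in the simulations, which reached 89.5%. Of the 287 genes that changed in wild type, 256 (89.2%) had the same sign in the amp1-13 difference; they were picked with the shared DMSO arrays, which by itself favours equal signs, and no simulation was made for them. The overlap was 1628 without DMSO array 1 of wild type, 0 and 3 without DMSO arrays 2 and 3, 5, 1 and 0 without DMSO arrays 1, 2 and 3 of amp1-13, and 4, 1 and 3 without hyperphyllin arrays 1, 2 and 3 of wild type.

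The hyperphyllin responses of the genotypes share no array. They had 2 genes called in the same direction, AT4G15700 and AT4G15660, where independent lists would share 0.0232 up and 0.0048 down. Across genes the fold changes correlated with r = 0.32, with a slope of the amp1-13 response on the wild-type response of 0.20. The same simulations of unchanged groups, with the same limit, gave r from -0.88 to 0.861. Over all genes 57.6% had the same sign, within the 17.3% to 81.6% of the simulations. Of the 287 genes called in wild type, 226 (78.7%) had the same sign in amp1-13, a share for which no simulation was made, with a median change in the wild-type direction of 0.81 in wild type and 0.22 in amp1-13. STZ, for example, was at group means of 9.40 in DMSO and 9.38 in hyperphyllin in amp1-13, against 6.73 and 10.03 in wild type. Its amp1-13 DMSO arrays ran from 8.56 to 10.38, and its wild-type DMSO arrays were at 8.43, 5.81 and 5.96. Handling that differed between samples may account for part of its rise in wild type, as described below. The genes were chosen by their change in wild type, which by itself makes the amp1-13 median smaller. The overlap was 87 without DMSO array 1 of wild type and 1 without DMSO array 2 or hyperphyllin arrays 2 or 3 of wild type.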

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

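The tests of this part were chosen after the results had been seen, unless said otherwise. In the interaction of genotype and treatment, 5 gene sets stood out because camera called a difference between the responses of the genotypes to hyperphyllin. None of the 5 kept its call with an estimated correlation. They were the auxin response genes (camera adjusted p = 0.0442) and the stomatal lineage markers (camera adjusted p = 0.0442). The change with hyperphyllin was higher in amp1-13 for the auxin genes and lower for the stomatal markers, which does not describe their levels. The others were the genes of the chloroplast genome (adjusted p = 2.43e-05, 60 of 63 lower), the U-box ligase family PUB (adjusted p = 5.87e-05, all 10 lower) and the cytochrome P450 family CYP (adjusted p = 0.0214, 20 of 28 lower). The last 3 sets were chosen after seeing the data. With an estimated correlation the adjusted p values were 0.444, 0.248, 0.772, 0.649 and 0.286 in this order. Random draws of the treatment labels within each genotype gave at least 2 shifted lists in 28 of 100 draws, and up to 5, so a chance origin of the list result is not excluded.

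Probe sets without a gene name here, which the report uses only in the alternative with all probe sets, also held calls. There were 59 with hyperphyllin in wild type (45 higher, 14 lower), 1 with hyperphyllin in amp1-13, 22 between the genotypes in DMSO (3 higher, 19 lower) and 107 between hyperphyllin-treated wild type and DMSO-treated amp1-13 (43 higher, 64 lower). What these probe sets measure was not determined, and no biological explanation was tested.

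DMSO array 1 of wild type stood apart from arrays 2 and 3, and 4 explanations were weighed. All tests of it were chosen after the arrays had been examined, and some were replaced after their results were seen. The first versions put array 1 at 1.06 on an axis from wild type (0) to amp1-13 (1) in DMSO and at 0.993 on an axis from DMSO (0) to hyperphyllin (1) in wild type, but arrays 2 and 3 define the 0 of both axes, so these values cannot tell the explanations apart. The 0.993 had at first been read as matching hyperphyllin-treated wild type, and a first ranking over the other 11 arrays had left a poor measurement open. Over the 40 genes called between the genotypes in hyperphyllin, where 0 marks amp1-13 in DMSO and 1 the wild-type side, array 1 lay at 0.148, against 0.468 and 0.409 for arrays 2 and 3 and -0.0856 to 0.0689 for amp1-13. This lay outside the range of the amp1-13 arrays but closer to it than arrays 2 and 3. The distance was within the margin that the test allowed, so amp1-13 RNA on array 1 remained possible. The same 0.148 leaves open that arrays 2 and 3 share a difference in growth or handling.

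Single genes differed from this picture without excluding it: TAPX was at 7.92 there, against 7.88 and 7.83 on arrays 2 and 3 and 8.57 to 8.68 in amp1-13. AT4G15700 was at 1.86, against 1.52 and 1.65 and 2.90 to 3.42. TAPX was picked with array 1 counted as wild type. AT4G15700 also passed in comparisons that do not compare array 1. These were hyperphyllin in amp1-13 (limma adjusted p = 3.96e-04) and the genotypes in hyperphyllin (limma adjusted p = 0.00964). RNA of hyperphyllin-treated wild type did not match, since 637 genes were called between array 1 and those arrays, against 36 between array 1 and amp1-13 in DMSO, where setting DMSO array 2 of amp1-13 apart from its own group called 46 and setting arrays 1 or 3 apart called 0. Each hyperphyllin array of wild type set apart from its group called 0. Such counts set 1 array against a group and assume that it varies like the other groups. A poor measurement was not excluded. The mean correlation of array 1 with the other groups ranked 9 of 12 from the lowest. That mean leaves out arrays 2 and 3 of its own group, whose own means were the lowest (0.977 and 0.9755). The means of the arrays in the other groups include arrays 2 and 3, which lowers them, so the ranking cannot decide. The limits for these last 2 tests were written after their values were known. The identity of the array could therefore not be settled, and without it the count in wild type was 2449.

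The 16 genes that rose at least 4-fold with hyperphyllin in wild type, STZ among them, also varied together as a set inside the amp1-13 groups. Their spread there lay at a median percentile of 99.7 among genes of like level, and their deviations correlated with a median r of 0.967, against at most 0.441 in 1000 random sets. STZ ran from 8.56 to 10.38 in DMSO-treated amp1-13, and 15 of the 16 followed the others more closely than any random set. The defensin-like gene PDF1.4 did not (percentile 87.9, median r of 0.0204 with the others). PUB23 and AR781, which rose by less than 4-fold, were outside this test. Like STZ they were highest on DMSO array 2 and on hyperphyllin array 1 within the amp1-13 groups. Handling that differed between samples may therefore account for part of the rise of the 16 genes other than PDF1.4 (99.7), and of PUB23 and AR781. A true response to hyperphyllin was not separated from it, and this was untested.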

How the results depend on the processing

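Of 277 alternatives to the 15 counts, 130 stayed within 1.5 times the count and 147 did not; where no reason is given, the cause was not tested. Signal over background of single probes was not available. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated with r from -0.281 to 0.295 (4 of 18 pairs over 0.1), and 5 of 12 arrays were closest to their own number. With the replicate number as a block, hyperphyllin in wild type gave 189 genes, the genotypes in DMSO 2 (2 of at least 2-fold), the genotypes in hyperphyllin 15 and the overlap on shared controls 2; the block changed no other count by over 1.5 times. The values below follow the order hyperphyllin in wild type (then at least 2-fold), hyperphyllin in amp1-13 (2-fold), genotypes in DMSO (2-fold), genotypes in hyperphyllin, interaction, treated wild type against amp1-13 in DMSO, overlap on shared controls and overlap of the responses. Array weights, which gave DMSO array 1 of wild type 0.196, gave 3026, 567, 102, 19, 2663, 462, 569, 290, 845, 1585 and 57. Leaving out 1 array gave 23 to 2449, 18 to 626, 2 to 5, 2 to 4, 0 to 2672, 0 to 612, 1 to 11, 0 to 482, 39 to 124, 0 to 1628 and 1 to 87; fewer arrays lower the power. Leaving out DMSO array 1 of wild type where it is not compared gave 138 and 23 for hyperphyllin in amp1-13, 577 for the genotypes in hyperphyllin and 633 for treated wild type against amp1-13. With array 1 alone for its group, assumed to vary like the other groups, hyperphyllin in wild type gave 531 and 182, the genotypes in DMSO 33, the interaction 262 and the responses shared 13. The compared groups alone gave 38 and 15 for hyperphyllin in amp1-13, 0 and 0 for the genotypes in DMSO, 375 in hyperphyllin, 442 for treated wild type against amp1-13 and overlaps of 0 and 5. A trended and robust prior gave 32 and 10 for hyperphyllin in amp1-13, 116 and 25 for the genotypes in DMSO, 63 in hyperphyllin, and overlaps of 37 and 15. Quantile normalization gave 11, 5 and an overlap of 5 for the genotypes in DMSO, and centring on medians 7, 4 and 4. All probe sets gave 10 and 9 for hyperphyllin in amp1-13, 27 and 23 for the genotypes in DMSO, 26 in hyperphyllin, 272 for treated wild type against amp1-13 and an overlap of 3. Without the dimmest probe sets hyperphyllin in amp1-13 gave 11 and 5, and the responses shared 6. An adjusted p of 0.01, stricter by construction, gave 24 and 18 for hyperphyllin in wild type, 2 and 2 for the genotypes in DMSO, 1 in hyperphyllin, and 57 for treated wild type against amp1-13, and 2-fold in both parts left overlaps of 5 and 1. Shifted lists (hyperphyllin in wild type, in amp1-13, genotypes in DMSO, interaction) numbered 0, 0, 0 and 0 with an estimated correlation; fry gave 0, 1 and 0 for the last 3. Leaving out 1 array gave 0 to 4, 0 to 3, 2 to 5 and 0 to 4, the compared groups alone 1 and 3 for the first 2, removal of the dimmest probe sets 0 for the first and last, and array 1 alone 0 for the last 2. For named genes, 169 results had 2670 alternatives. With array 1 alone the sign turned for EXPA7 with hyperphyllin in wild type (0.0229), for LBD29 (0.0209), XTH16 (-0.0144), GSTU20 (-0.49) and LAMP1 (AT5G19740; 0.13) between the genotypes in DMSO, for LAMP1 in the interaction (-0.11), and for the flavonoid list between the genotypes in DMSO (-0.0317) and the auxin list in the interaction (-0.22). LAMP1 between the genotypes in hyperphyllin turned to -0.0425, -0.0113 and -0.00387 without hyperphyllin array 3 of amp1-13 and arrays 2 and 3 of wild type, in a range from -0.0425 to 0.0536 over the arrays left out.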

Other observations

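A run of 5 neighbouring CC-type glutaredoxin genes, AT4G15660 to AT4G15700, had higher means in 4 comparisons. It was chosen after its values were seen. All 5 were measured and all 5 were higher with hyperphyllin in wild type (3 passed) and in amp1-13 (2 passed), and in amp1-13 against wild type in DMSO (1 passed) and in hyperphyllin (3 passed). AT4G15700 had group means of 1.68 and 3.67 in wild type without and with the compound, and in amp1-13 2.90 to 3.42 on the DMSO arrays and a mean of 5.28 with it. The genes are close copies, and whether probes are shared between them was not determined.

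A run of neighbouring genes of proline-rich and lipid-transfer type proteins, AT4G22460 to AT4G22530, also chosen after its values were seen, responded in wild type. Of 14 genes, 8 had a probe set of their own, 7 of these had higher means with hyperphyllin and 6 rose: AT4G22470 by 2.44 ± 0.40, AT4G22520 by 1.77, AT4G22490 by 1.31, AT4G22505 by 1.23, AT4G22485 by 1.13 and AT4G22513 by 1.03 (3 arrays per group). AT4G22460 was at -0.88 without passing (limma adjusted p = 0.0818). With hyperphyllin in amp1-13, 6 of the 8 had higher means and none passed. None passed between the genotypes in hyperphyllin, and the interaction was called for 0 genes. In amp1-13 against wild type in DMSO, 7 had higher means and AT4G22520 alone passed (1.27 ± 0.21, limma adjusted p = 0.0463). AT4G22470 was among the 16 genes for which handling was weighed above. Whether probes are shared within this run was not determined.

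Among the 37 families chosen later, the genes of the chloroplast genome were shifted upwards with hyperphyllin in wild type (60 of 63 higher, 0 passed, camera adjusted p = 4.68e-09, adjusted p = 0.825 with an estimated correlation) and in amp1-13 against wild type in DMSO (56 higher, adjusted p = 7.7e-04, estimated 0.842). The PUB family was shifted upwards with hyperphyllin in wild type (8 of 10 higher, PUB23 rose, adjusted p = 0.0102, estimated 0.825). Handling that differed between samples may account for part of the rise of PUB23, as for STZ. In amp1-13 the glutathione transferase family GSTU was shifted downwards by hyperphyllin (9 of 11 lower, adjusted p = 0.0428, estimated 0.416) and the family CHR upwards (7 of 8 higher, adjusted p = 0.0428, estimated 0.416).

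Whether variants linked to AMP1 explain genotype differences was asked after the results were seen. Of 39 genes with a position called between the genotypes in hyperphyllin, 2 lay within 500 genes on either side of AMP1 (5.13%, against 3.77% of all measured genes; one-sided Fisher exact p = 0.436). The test cannot tell.

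Regrouping tests, also chosen after the results were seen, used all 10 splits of the 6 arrays of a comparison into groups of 3, which are too few to exclude chance. For hyperphyllin in wild type the real 287 genes ranked 2, with 350 as the highest other, the 2-fold count of 102 ranked 2 (highest other 137), and 5 splits gave at least the 2 shifted lists (highest other 3). The split with 350 sets DMSO arrays 2 and 3 of wild type and hyperphyllin array 3 against the other 3 arrays, which points to structure of the samples. The real grouping ranked 1 for hyperphyllin in amp1-13 (3 genes and 2 of at least 2-fold, highest other 0 for both), for the genotypes in DMSO (57, highest other 32; 15, highest other 12; 4 lists, highest other 3), for the genotypes in hyperphyllin (40, highest other 0) and for treated wild type against amp1-13 (177, highest other 0). For the lists with hyperphyllin in amp1-13, 3 splits gave at least 1 (highest other 2).

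For the interaction the real count was 0 genes, which all 100 draws of the treatment labels reach by construction, so the test decided nothing; the highest draw gave 282. The overlap of the responses of the genotypes, AT4G15700 and AT4G15660, was reached in 1 of 100 draws, the real one (highest other 0). No other split of the amp1-13 arrays called a gene, so this adds nothing to the 10 splits, which are too few. The overlap of 20 genes on shared controls, TAPX among them, was reached in 3 of 100 draws, the real one included. The highest other draw gave 107, several times the real value, which points to structure of the samples.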
